A study of Mus musculus with 3 samples.

How the data were processed

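Islets of 3 female NOD-SCID mice were measured by 10x Genomics single-cell 3′ RNA sequencing, with 1 library per mouse and no pooling. Per the labels, islets were isolated by collagenase perfusion through the bile duct and a density gradient, and were dissociated with TrypLE. The deposited matrices hold counts, as whole numbers of unique molecular identifiers (UMIs) per gene and barcode, for barcodes that had already been selected; how they were selected is not stated. The labels name Cell Ranger 2.2 with mm10 and the v2 protocol, while the matrix headers name software version 3.1.0, and the counts were used as deposited. The feature list has 31053 Ensembl gene IDs, of which 30934 were found in GENCODE M21 (GRCm38, which is mm10) and 119 were not, so positions are given for matched genes. All libraries carry the same list, and 71 IDs share a symbol with another. The libraries held 32389170, 48076507 and 57849496 UMIs, with medians of 1777, 3587 and 4082 UMIs and 315, 741 and 1340 genes per barcode in mice 1, 2 and 3. Mice 1 and 2 shared 148 barcodes, of which 14 were kept cells in both, against 9 and 13 shared barcodes for the other pairs.

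Cells with at least 500 genes and at most 15% mitochondrial UMIs were kept (1145, 2705 and 3640). Doublet scores came from Scrublet in scanpy 1.11.5 (exact neighbours, seed 1), and the highest scores were removed at a rate of 0.8% per 1000 barcodes, which took out 55, 96 and 166 cells. Scrublet's automatic threshold marked 22 of 7490 cells (0.294%), too few for libraries of this size, and was run as an alternative. Counts were scaled to 10000 per cell and log-transformed. Clusters were made from 126 marker genes of 18 cell types fixed before the data were examined, with values scaled and limited to 10, 20 principal components, exact 20 nearest neighbours, shared-neighbour weights and the Leiden method (leidenalg 0.10.2, igraph 0.11.9, resolution 1, seed 1). A cluster took a cell type's name when at least 3 of that type's markers were among its 30 leading genes, 1 or more of them in its first 10, no other type had more there, and at least 3 were raised 2-fold, with a pseudocount of 20 CPM and detection in at least 10% of its cells. Libraries were merged without integration. Some clusters came mostly from 1 mouse, such as an alpha-like cluster with 755 of 849 cells from mouse 3. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

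UMIs were summed per mouse and class for endocrine classes with at least 20 cells in every mouse, and beta-like, alpha-like and delta-like sums entered 1 fit with the mouse as a block. The fit used edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, robust glmQLFit, glmQLFTest, Benjamini-Hochberg over all genes tested, FDR 0.05), with 12185 genes tested. The marker genes are left out of the counts of calls and of the list tests, so that no counted gene entered the clustering. The naming of clusters ranked all genes, so other genes could affect whether markers reached the leading ranks. The pairing by mouse was checked on 4810 genes, where differences from the class mean correlated at 0.276 to 0.699 for classes of the same mouse and at -0.639 to 0.198 for classes of other mice. Gene lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01 with a prior count of 2, and with an estimated correlation. The named genes of each contrast are, by a rule fixed before the data were examined, the 10 largest fold changes in each direction among genes past FDR 0.05 that are not markers, changed the same way in every mouse, differ by at least 1 on the log2 scale, reach a mean of 50 CPM in the higher class and do not carry a numbered gene-model symbol. Up to 4 members per list with the smallest p are named besides. A few genes that these rules pick are not named in the text or figures. CPM beside edgeR results are scaled by TMM, and levels of Neurog3, Fam241b and Fev, and of Spp1 where so stated, are CPM of the class's summed UMIs without TMM.

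The 22 lists, with 329 genes of which 2 were not in the feature list, are hormones, beta-cell transcription factors, glucose sensing and insulin secretion, hormone processing and granules, genes disallowed in beta cells, immature beta cell, endocrine progenitor, pancreatic progenitor, acinar, duct, cell cycle, ER stress and protein folding, dissociation response, interferon and antigen presentation, MHC class II, islet autoantigens, glycolysis, oxidative phosphorylation, antioxidant defence, receptors of islet paracrine signals, glutamate and GABA handling, and cell adhesion and axon guidance. Non-endocrine genes in beta-like cells were tested in the same way against the mean of endothelial-like and macrophage-like sums. Double cells carry at least 3 beta markers other than Ins1, Ins2 and Iapp and at least 3 markers of another type. Cycling cells carry at least 3 cell cycle genes, and were counted again after thinning to 2000 UMIs. A hormone counted as above background at 5 times its pooled share in that mouse's endothelial-like and macrophage-like cells and at least 10 UMIs. Shares of cells carry exact Clopper-Pearson 95% intervals, and a count of 0 is given with the share that 3 counts would make.

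The fits were tested on simulated data made from the sums with known folds added. A 2-fold change was recovered for 78.0% of genes for beta against alpha, 77.6% for beta against delta and 68.8% for alpha against delta, and a 1.25-fold change for 14.0%, 6.12% and 6.00%. False calls were 8 of 145, 6 of 114 and 14 of 120. The simulated classes shared 1 mean profile, without mouse effects and with few changed genes. The real fits called 5908, 5417 and 5092 genes, so these rates need not hold for them. Alternatives fixed before the data were examined were other gene minimums (250 and 1000), 10% mitochondrial UMIs, doublets kept, the automatic doublet threshold, clusters from the 2000 most variable genes, resolutions 0.5 and 2, DESeq2 size factors, the Wald test of DESeq2 1.42.0, no gene filter, no mouse block, only the classes compared in the fit, hormone genes removed, free RNA subtracted, cells thinned to 2000 UMIs, classes from hormone UMIs alone, and each mouse left out. For the subtraction of free RNA, the profile was that of all barcodes of a library, kept cells included. Its amount was set by the lowest level of a hormone of another cell type. A minimum of 5000 UMIs, gamma-like contrasts at 10 cells per mouse and duct-like against endocrine cells were added after the data were seen. Reads were not available, so alignment and barcode selection were not repeated.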

Results

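Islets of Langerhans from 3 non-diabetic female NOD-SCID mice, a strain without mature T and B cells that does not develop the autoimmune diabetes of NOD mice, were profiled by droplet-based single-cell RNA sequencing of transcript 3′ ends. The mice were 10 to 11 weeks old, gave 1 library each and form 1 group. The series title asks about a non-endocrine source of regenerated beta cells, but the labels of these libraries name no injury, treatment or regeneration. The comparisons therefore lie between cell classes of the same mice, and p-values cover the spread of the class differences over the 3 mice. They do not cover the error of making the classes from the same cells. The libraries of mice 1, 2 and 3 held 32389170, 48076507 and 57849496 unique molecular identifiers (UMIs) over 6005, 4444 and 5713 barcodes. Filters kept 1090, 2609 and 3474 cells with medians of 6047.5, 5456 and 11394.5 UMIs per cell. Barcodes that were removed gave 29.2%, 16.3% and 1.98% of their UMIs to Gm42418, a gene model that overlaps ribosomal RNA, against 3.67%, 2.71% and 0.438% in kept cells. Binomial intervals and floors given here cover counting error only.

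The islets held all 4 main endocrine cell types and the usual duct, vascular and immune neighbours. Beta-like cells, marked by insulin, made up 21.8% ± 7.60 (SD, n = 3) of the 7173 kept cells, alpha-like cells, marked by glucagon, 17.1% ± 8.28, and delta-like cells, marked by somatostatin, 11.1% ± 5.49. Gamma-like cells, marked by pancreatic polypeptide, made up 3.19% ± 3.43, with 245 of the 280 cells from mouse 3. Duct-like cells (351) made up 5.54% ± 1.94, endothelial-like cells (376) 4.91% ± 1.89, acinar-like cells (158) 2.48% ± 1.94, macrophage-like cells (186) 2.42% ± 0.676, pericyte-like cells (160) 1.96% ± 1.21 and fibroblast-like cells (64) 0.791% ± 0.363. No name was reached for 1968 cells (28.7% ± 12.4), which had a median of 3585.5 UMIs. Some of them were rich in hormone RNA, such as a cluster of 569 cells (475 from mouse 2) with 13.4% Ins1 and 25.9% Ins2. Another, of 383 cells (318 from mouse 3), held 38.5% Gcg. Classes from hormone UMIs alone placed 851 unnamed cells in the insulin class and 144 in the glucagon class. The shares of beta-like and alpha-like cells leave these cells out. Whether they are shallow endocrine cells or hold free RNA was not tested. Among the unnamed cells, 1 cluster of 105 cells was led by the Schwann cell genes Fabp7 and Cryab, and 1 cluster of 74 cells by the antigen-presentation genes H2-Ab1, H2-Aa and Cd74. Both sets of names were chosen after their values were seen. Beta-like cells were shallow in part as well, with clusters of 334 and 317 cells at medians of 4791 and 3156 UMIs. The class medians were 4540.5, 10336.5 and 28496 UMIs in mice 1, 2 and 3. The share of beta-like cells was 28.1%, 23.9% and 13.3% in mice 1, 2 and 3. It depended on the clustering, at 10.6% when clusters came from the 2000 most variable genes, 10.8% at resolution 0.5 and 11.4% with at most 10% mitochondrial UMIs. The share of acinar-like cells rose to 7.51%, 22.1% and 0.782% in mice 1, 2 and 3 with at least 250 genes per cell, and to 5.05%, 12.5% and 0.547% with the most variable genes. The share of duct-like cells was 2.70% with the most variable genes, and that of alpha-like cells 27.6% among cells with at least 5000 UMIs. Cells with several lymphoid markers were rare, as 9 of the 7173 kept cells carried at least 3 T cell markers, and 0 carried at least 3 B cell markers. This allows a share of up to 0.0418% for cells with 3 detected B cell markers. It does not limit the share of B cells, which may hold fewer detected markers at this depth.

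**Figure D1:**
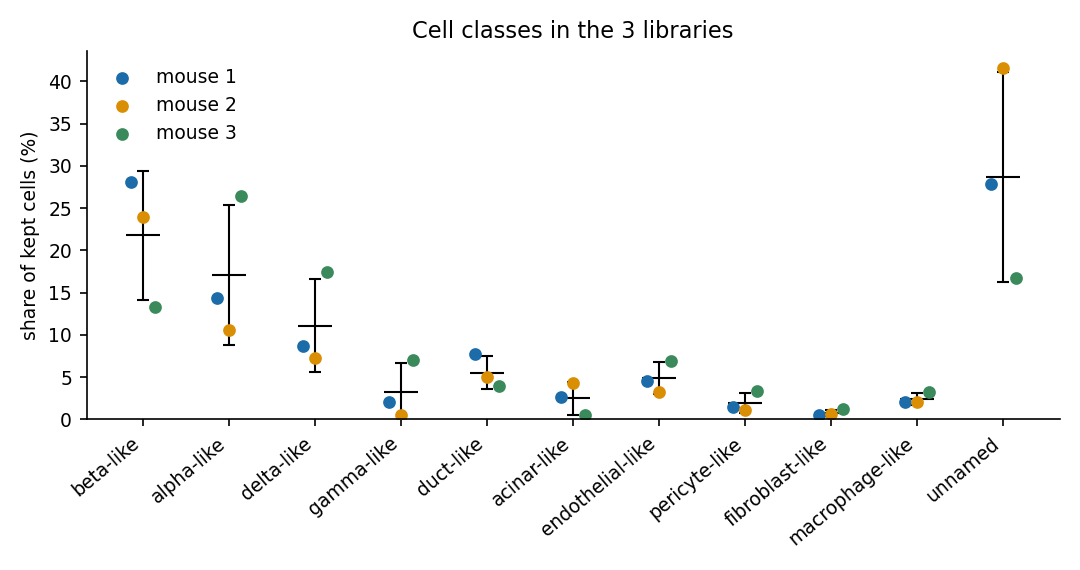
Share of kept cells (percent, vertical axis) in each cell class, with 1 point per mouse, a line at the mean and bars of 1 SD over the 3 mice. Beta-like cells made up 21.8%, alpha-like 17.1% and delta-like 11.1% of kept cells on average.

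Hormone transcripts filled much of each endocrine cell. Ins1 (ENSMUSG00000035804, GRCm38/mm10 chromosome 19, 52264297 to 52265476) and Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381), the mouse insulin genes, together gave 63.1% ± 2.86 (SD, n = 3) of the UMIs of beta-like cells, with an Ins2 to Ins1 ratio of 2.36 ± 0.246. Gcg, the glucagon gene (ENSMUSG00000000394, chromosome 2, 62474530 to 62483650), gave 44.6% ± 1.39 of the UMIs of alpha-like cells. Sst, the somatostatin gene (ENSMUSG00000004366, chromosome 16, 23889573 to 23890958), gave 19.4% ± 2.14 in delta-like cells, which also held 2.64% ± 0.253 Iapp, the amylin gene, close to the 2.68% ± 0.091 of beta-like cells. These are shares of all UMIs, of which insulin took 63.1% in beta-like cells. With TMM factors of 0.605 to 0.730 for beta-like and 1.46 to 1.67 for delta-like sums, the scaled level of Iapp was higher in beta-like cells. Ppy, the pancreatic polypeptide gene (ENSMUSG00000017316, chromosome 11, 102099930 to 102101319), gave 30.4% ± 3.67, Pyy 12.5% ± 2.32 and Gcg 7.95% ± 3.47 of the UMIs of gamma-like cells. Endothelial-like and macrophage-like cells, which do not make insulin, held 4.16%, 3.75% and 1.51% insulin UMIs in mice 1, 2 and 3.

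**Figure D2:**
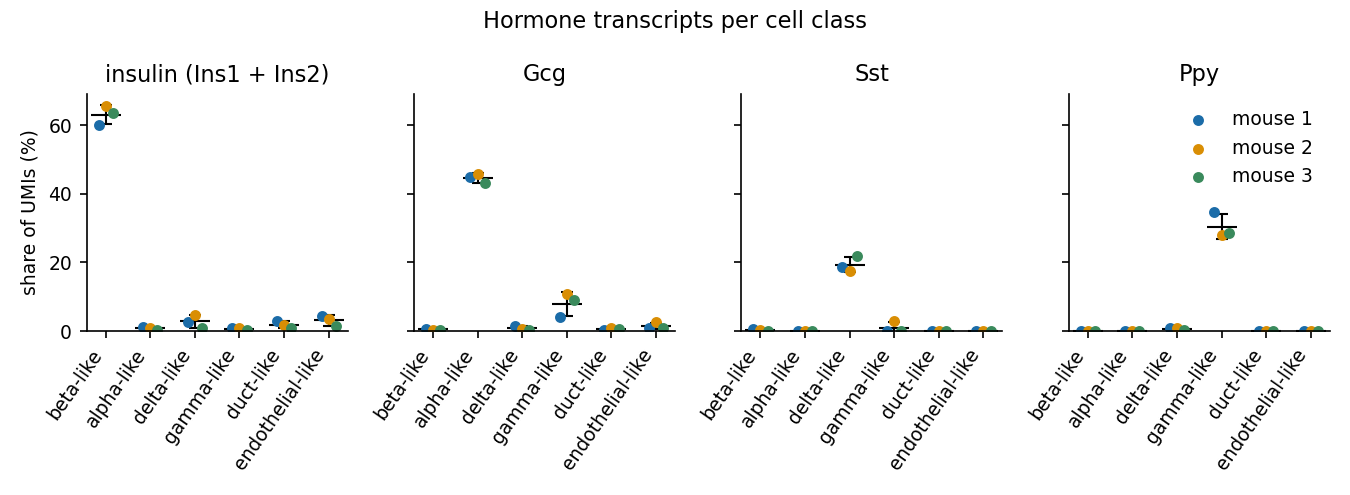
Share of each cell class's UMIs (percent, vertical axis) taken by insulin, Gcg, Sst and Ppy, in beta-, alpha-, delta-, gamma-, duct- and endothelial-like cells, with 1 point per mouse, a line at the mean and bars of 1 SD. Insulin gave 63.1% in beta-like cells, Gcg 44.6% in alpha-like cells, Sst 19.4% in delta-like cells and Ppy 30.4% in gamma-like cells.

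Beta-like and alpha-like cells were compared to describe what sets insulin-producing cells apart beyond their hormone. Pcsk1, the prohormone convertase that cleaves proinsulin (ENSMUSG00000021587, chromosome 13, 75089826 to 75134861), was 85.3-fold higher in beta-like cells, at 271 ± 83.9 TMM-scaled CPM (the level relative to all counts of the class; SD, n = 3) against 3.94 ± 2.75 (log2 fold change 6.42, SE 0.35, edgeR adjusted p = 8.27e-05). Plut, a long noncoding RNA next to Pdx1 (ENSMUSG00000092570, chromosome 5, 147228596 to 147271521), was 155-fold higher (76.6 ± 19.3 against 0.701 ± 0.502 CPM; log2 7.27, SE 0.44, adjusted p = 5.89e-05), and Trpm5, a calcium-activated cation channel (ENSMUSG00000009246, chromosome 7, 143069153 to 143094642), 119-fold higher (166 ± 48.1 against 1.83 ± 0.842 CPM). In the other direction Pdk4, a kinase that shuts off pyruvate dehydrogenase (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309), was 68.0-fold higher in alpha-like cells (51.4 ± 17.8 against 0.741 ± 0.153 CPM; log2 -6.09, SE 0.21, adjusted p = 1.49e-19), and Higd1a, a mitochondrial protein, 48.5-fold higher (180.2 ± 40.1 against 3.97 ± 1.56 CPM). The other genes of the largest differences toward beta-like cells were AC078895.1 (7.12), Bace2 (6.62), Npy (6.62), Angptl7 (6.58), Fam151a (6.49), Tmem215 (6.48) and Itpkb (6.35), as log2 fold changes. Toward alpha-like cells they included Edn3 (-5.87), Ctxn2 (-5.31), Vwde (-4.98), Basp1 (-4.87), Ndst4 (-4.86), the oxytocin receptor gene Oxtr (-4.64) and Pappa2 (-4.56). Each of these genes moved the same way in all 3 mice. Of 12185 genes tested, leaving out the genes used for clustering from the counts, 2934 were higher and 2974 lower in beta-like cells at FDR 0.05, and 1023 and 1124 of these differed at least 2-fold.

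**Figure D3:**
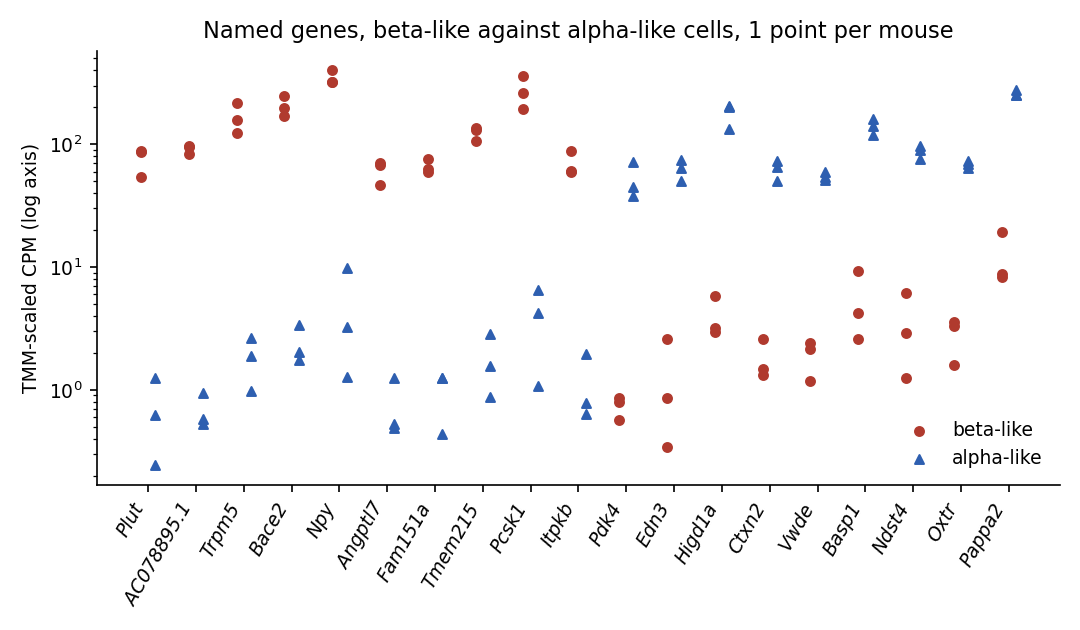
TMM-scaled CPM (vertical axis, logarithmic) of genes named for the beta-like against alpha-like comparison, with 1 point per mouse and class. Pcsk1 lay at 271 in beta-like and 3.94 in alpha-like cells on average, and Pdk4 at 0.741 and 51.4.

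By gene list, glucose sensing and protein folding were higher in beta-like than alpha-like cells. Of 18 tested genes of glucose sensing and insulin secretion, 11 were higher, 2 lower and 5 did not pass, with the incretin receptor genes Glp1r (log2 4.70) and Gipr (1.90), Prkca (1.70) and Syt13 (1.04) higher (camera adjusted p = 0.0129, and adjusted p = 0.600 with an estimated correlation). The list of ER stress and protein folding had 14 of 20 genes higher, 3 lower and 3 not passing (adjusted p = 0.0129, and adjusted p = 0.600 with an estimated correlation). Glucose sensing did not pass with clusters from the most variable genes (adjusted p = 0.0515), nor ER stress in cells thinned to 2000 UMIs (7 of 19 higher, adjusted p = 0.0561). Edem1 (2.74), Sel1l (1.24) and Dnajc3 (1.13), which act in folding and degradation in the ER, were higher, and the stress factor gene Atf3 was lower (-3.48). Of 11 transcription factor genes of beta cells, 5 were higher, 1 lower and 5 not passing, among them Mnx1 (5.49), Mlxipl (4.04), Insm1 (1.29) and Pax6 (0.81), and the list passed with free RNA subtracted (adjusted p = 0.0495), in thinned cells (0.048) and without mouse 2 or mouse 3. Receptors of islet paracrine signals (14 tested) had 8 higher and 4 lower, with the glucagon receptor gene Gcgr (5.40), the muscarinic receptor gene Chrm3 (4.75) and Galr1 (3.83) higher and Ffar4 lower (-2.80). Oxidative phosphorylation (17 tested) had 7 higher and 2 lower, led by Cox6a2 (4.88) and Cox5a (0.85). Glycolysis (13 tested) had 4 higher and 2 lower, with Pkm (1.14), Pgk1 (0.50) and Ldhb (1.18) higher. Of 9 genes that mature beta cells are known to keep low, 4 were lower (Hk1 -4.66, Oat -3.45, Igfbp4 -3.11, and Arap2 -1.84 but 0.78 with classes from hormone UMIs alone), 2 higher and 3 not passing, and with at least 1000 genes per cell the list passed as lower (adjusted p = 0.0173).

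Interferon and antigen presentation genes were lower in beta-like than alpha-like cells, and the other lists given here did not pass. Interferon and antigen presentation had 10 of 19 genes lower in beta-like cells, 1 higher and 8 not passing, with B2m (-0.96), Bst2 (-1.19), H2-K1 (-0.59) and Psmb8 (-0.58) lower (adjusted p = 0.0394, and adjusted p = 0.600 with an estimated correlation). With classes from hormone UMIs alone these 4 genes turned (1.57, 1.84, 1.30 and 0.45), but the insulin class of that setting is mixed, with 1260 beta-like, 208 duct-like, 130 endothelial-like, 87 acinar-like, 86 macrophage-like and 851 unnamed cells among others. The list did not pass without mouse 1, with clusters from the most variable genes (adjusted p = 0.0657) or in thinned cells (1 of 10 lower, adjusted p = 0.342). The dissociation response, a set of early stress genes that tissue digestion induces, had 9 of 16 lower and 3 higher, including Zfp36 (-1.37), Fos (-1.17) and Egr1 (-0.86). Of 18 hormone processing and granule genes, 5 were higher and 9 lower, with Nnat (4.47) and Scg2 (1.47) higher and Vgf (-3.20) and Pam (-1.61) lower. The endocrine progenitor list (12 tested) had 6 higher and 3 lower, Btbd17 (1.78) and Insm1 among the higher and Fev (-3.65) and Gadd45a (-1.15) among the lower. The immature beta cell list (7 tested) had 2 higher (Npy and Dlk1, 2.78) and 3 lower (Cd81 -2.81, Serpina7 -2.95, Gast -2.78), and the pancreatic progenitor list (4 tested) had 1 lower, Gata6 (-3.33). The cell cycle list had 3 of 18 lower (Mcm6 -1.57, Mcm5 -1.46, Pcna -0.68) and 15 not passing, and passed as lower without mouse 2 or mouse 3. Antioxidant defence (20 tested) had 6 higher and 6 lower, with Nqo1 (2.62) higher and Prdx4 (-1.51), Prdx2 (-0.59) and Prdx5 (-0.49) lower. Islet autoantigens (7 tested) had 2 higher (Gad1 3.53, Ica1 0.45) and 1 lower (Ptprn2 -0.40, but 0.052 in thinned cells). Glutamate and GABA handling (6 tested) had 3 higher (Gad1, Abat 1.41, Glul 1.04) and 2 lower. Cell adhesion and axon guidance (14 tested) had 6 higher and 5 lower, with Robo1 (2.12) and Cdh1 (1.34) against Sema3e (-2.85) and Ncam1 (-1.33). MHC class II (5 tested) had 1 higher, H2-Eb1 (1.91), and the ghrelin gene Ghrl, the only tested hormone gene outside the markers, was higher (0.74) in 2 of 3 mice. Both turned with clusters from the most variable genes (H2-Eb1 -0.24, Ghrl -0.21), and Ghrl also with at least 1000 genes per cell (-0.19).

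The duct list (14 tested) had 5 genes higher in beta-like cells, with Cldn7 (1.06) and Dcdc2a (2.60) among them, and 5 lower, with Krt8 (-0.80, but 0.17 with classes from hormone UMIs alone) and Onecut2 (-1.63). The acinar list had 14 of 18 higher, 0 lower and 4 not passing (adjusted p = 0.0013, and adjusted p = 0.600 with an estimated correlation), with Bhlha15 (2.82), Cel (0.73), Pnliprp1 (0.72) and Ctrl (0.68). Without TMM scaling, acinar markers gave 0.281% ± 0.249 (SD, n = 3) of the UMIs of beta-like cells and 0.257% ± 0.250 of alpha-like cells, against 1.15% ± 0.994 of endothelial-like cells. The median log2 fold change of the acinar list turned from 0.62 to -0.50 with at least 1000 genes per cell (14 of 18 lower) and to -0.38 with clusters from the most variable genes, where Cel, Pnliprp1 and Ctrl turned as well. It was 0.44 with at least 5000 UMIs, 1.11 with free RNA subtracted (1 of 18 higher) and 1.83 in cells thinned to 2000 UMIs (15 of 15 higher). Adjusted over the list alone, the counts rose to 7 higher for endocrine progenitors, 15 for ER stress, 4 for dissociation and 7 for antioxidant defence, and stayed as given for the other lists. Median and mean differed in sign for granule genes (-0.22 and 0.22), the immature list (-0.17 and 0.16) and autoantigens (-0.07 and 0.48), and the test of antioxidant defence pointed down against a median of 0.03. Camera adjusted p lay between 0.053 and 0.864 for the lists without one given. The DESeq2 Wald test called 3884 genes, and cells thinned to 2000 UMIs gave 1529 of 5868 tested.

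Beta-like and delta-like cells were compared in the same fit. Prlr, the prolactin receptor gene (ENSMUSG00000005268, chromosome 15, 10177238 to 10349180), was 51.3-fold higher in beta-like cells, at 435 ± 99.7 CPM (SD, n = 3) against 10.1 ± 6.14 (log2 5.68, SE 0.45, edgeR adjusted p = 0.000676). Tmem215 (ENSMUSG00000046593, chromosome 4, 40472180 to 40477168), a membrane protein gene, was 98.5-fold higher (log2 6.62, SE 0.30, adjusted p = 1.03e-07). Delta-like cells held 26.8-fold more Ly6h (ENSMUSG00000022577, chromosome 15, 75551268 to 75567255), a neuronal surface protein gene, at 309 ± 26.6 against 12.7 ± 9.83 CPM (log2 -4.75, SE 0.66, adjusted p = 0.00507), and 22.7-fold more Arg1, the gene of arginase (206.8 ± 27.1 against 9.28 ± 6.96 CPM). The other genes of the largest differences were Angptl7 (6.39), AC078895.1 (6.11), Prss53 (6.07), Trpm5 (5.88), Bace2 (5.85), Papss2 (5.68), Ociad2 (5.55) and Plut (5.43) toward beta-like cells. Toward delta-like cells they were Ppp1r17 (-4.96), Gap43 (-4.41), Cfap61 (-4.37), Cd24a (-4.35), Tspan12 (-4.32), Ptn (-4.24), Caly (-4.10) and Basp1 (-4.05), with Gap43, Ptn and Basp1 known from growing axons. All 20 moved the same way in all 3 mice. At FDR 0.05, 2677 genes were higher and 2740 lower in beta-like cells, 855 and 1351 of them at least 2-fold.

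Protein folding and glucose sensing genes were higher in beta-like than delta-like cells. ER stress and protein folding had 17 of 20 genes higher, 2 lower and 1 not passing, with Calr (1.16), Atf4 (1.05) and Edem1 (1.34) higher and Atf3 lower (-1.82; camera adjusted p = 0.000109, and adjusted p = 0.606 with an estimated correlation). Glucose sensing and insulin secretion had 10 of 18 higher, 3 lower and 5 not passing, with Prkca (1.81), Gipr (1.85), Syt13 (1.45) and Cacna1d (1.33; adjusted p = 0.0131, and adjusted p = 0.626 with an estimated correlation). Oxidative phosphorylation had 11 of 17 higher, 0 lower and 6 not passing, with Cox6a2 (4.18), Cycs (0.78), Atp5g1 (0.65) and Cox5a (0.63; adjusted p = 0.0194, and adjusted p = 0.606 with an estimated correlation). This list did not pass with clusters from the most variable genes (5 of 17 higher, median 0.14, adjusted p = 0.186) or in thinned cells (0 of 16 higher, median 0.02 against 0.32, adjusted p = 0.989). The genes that beta cells keep low were lower for 6 of 9 and higher for 0, with Acot7 (-4.67), Ldha (-2.42), Arap2 (-2.38) and Smad3 (-2.20; adjusted p = 0.0248, adjusted p = 0.606 with an estimated correlation, and adjusted p = 0.0593 with free RNA subtracted). Interferon and antigen presentation had 11 of 19 lower and 0 higher, with H2-T23 (-1.56), H2-D1 (-0.79), Psmb8 (-0.79) and H2-K1 (-0.75; adjusted p = 0.0131, and adjusted p = 0.606 with an estimated correlation). With classes from hormone UMIs alone H2-D1 (0.28), Psmb8 (0.20), H2-K1 (1.17), Ldha (2.04) and Arap2 (0.14) turned, in an insulin class of which 1260 cells were beta-like and most others duct-like, endothelial-like or unnamed. In thinned cells the interferon list did not pass (2 of 10 lower, adjusted p = 0.493), and neither it nor oxidative phosphorylation passed without mouse 2. Transcription factors of beta cells (11 tested) had 5 higher, Mnx1 (5.84), Neurod1 (1.24) and Nkx2-2 (1.17) among them, and 2 lower, with Isl1 at -1.40. Receptors (14 tested) had 7 higher and 5 lower, with Galr1 (5.37) and Chrm3 (4.21) against Ffar4 (-3.46). Islet autoantigens (7 tested) had 3 higher, the zinc transporter gene Slc30a8 (5.13), Gad1 (5.09) and Chga (2.59), and 1 lower, Ptprn2 (-0.41), and passed as higher in thinned cells (adjusted p = 0.0267).

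An endocrine progenitor factor gene stood on the delta side. Cell adhesion and axon guidance, which did not pass (camera adjusted p = 0.0611, against 0.0449 with at least 1000 genes per cell, 0.0475 with clusters from the most variable genes and a pass without mouse 3), had 10 of 14 genes lower in beta-like cells and 4 higher, with Efna5 (-2.75), Epcam (-1.53) and Cdh2 (-1.47) against Robo1 (4.58). Neurog3, the transcription factor gene that starts endocrine differentiation in the embryo (ENSMUSG00000044312, chromosome 10, 62133090 to 62134763), was 4.89 log2 units higher in delta-like cells (SE 0.31, adjusted p = 4.47e-09; higher in 3 of 3 mice). A Neurog3 UMI was seen in 318 of 887 delta-like cells (35.9%, exact 95% interval 32.7 to 39.1; median 10674 UMIs), in 15 of 1393 beta-like cells (1.08%; median 10633 UMIs) and in 0 of 376 endothelial-like cells (median 4833 UMIs), where up to 0.798% with a UMI is allowed at that depth. Thinned to 2000 UMIs, a Neurog3 UMI was seen in 7.59% of delta-like, 0.231% of beta-like and 0 of 344 endothelial-like cells. The gene lies inside Fam241b on the opposite strand, and Fam241b was read at 65.8 CPM in delta-like and 9.36 CPM in beta-like cells. In the endocrine progenitor list (12 tested) 4 genes were higher, Gadd45a (1.12) and Btbd17 (1.03) among them, and 4 lower, with Neurog3 and Fev (-2.92). The pancreatic progenitor list (4 tested) had 1 higher, Hes1 (0.58, in 2 of 3 mice), and 2 lower, Nr5a2 (-2.87) and Gata6 (-1.78), both of which turned when classes came from hormone UMIs alone (0.77 and 0.092). Sox9, a marker of duct cells and pancreatic progenitors, had a UMI in 96 of 887 delta-like cells (10.8%), 10 of 1393 beta-like cells (0.718%), 264 of 351 duct-like cells (75.2%) and 2 of 376 endothelial-like cells (0.532%).

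**Figure D4:**
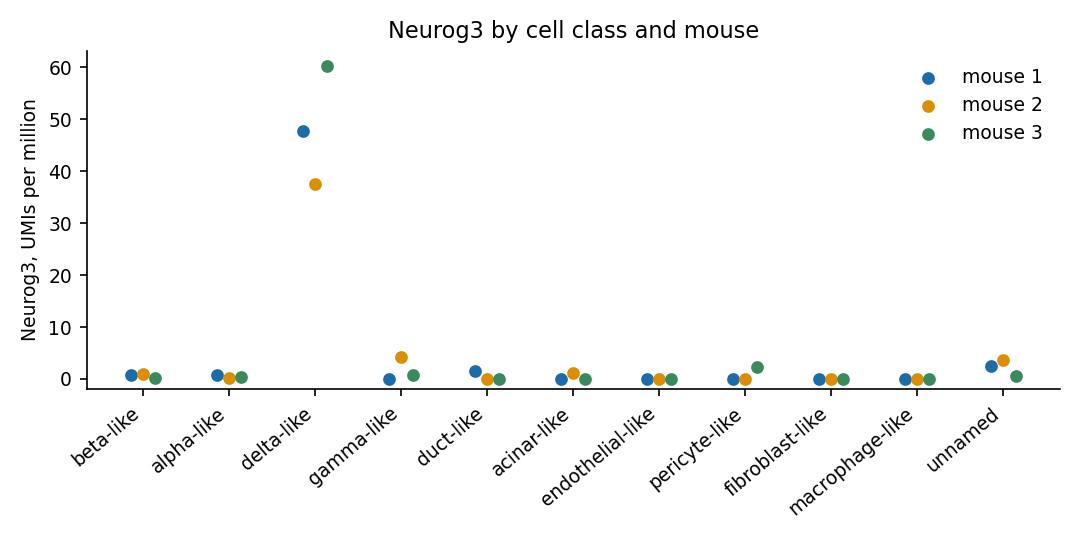
Neurog3 CPM (vertical axis) in each cell class, with 1 point per mouse. The delta-like cells of the 3 mice lie at 47.8, 37.5 and 60.2, above every other class.

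None of the remaining lists passed the camera test between beta-like and delta-like cells, though the duct and acinar lists did in other settings. The duct list had 1 of 14 higher and 7 lower, with Clu (-2.66), Slc4a4 (-2.55), Epcam and Cldn3 (-0.87), where Clu (0.73) and Cldn3 (0.90) turned when classes came from hormone UMIs alone. It passed as lower with at least 1000 genes per cell (adjusted p = 0.0288) and in thinned cells (adjusted p = 0.0267). The acinar list had 1 of 18 higher (Bhlha15, 1.28) and 0 lower, while acinar markers gave 0.634% ± 0.608 (SD, n = 3) of the UMIs of delta-like cells. The acinar list had 16 of 18 lower with at least 1000 genes per cell (median -0.89, adjusted p = 0.000171) and 12 lower with clusters from the most variable genes (median -0.47, adjusted p = 0.0475). It had 14 of 15 higher in thinned cells (median 1.07, adjusted p = 2.09e-05), and its median was 0.74 with free RNA subtracted. Granule genes (18 tested) had 6 higher and 5 lower, with Nnat (-2.0), Resp18 (-1.19), Chgb (-1.17) and Pam (-0.99). The immature list (7 tested) had 2 higher, with Npy at 2.99, and 3 lower, Dlk1 (-3.75), Cd81 (-2.48) and Gast (-2.48). Antioxidant defence (20 tested) had 8 higher and 7 lower, with Nqo1 (4.35) and Hmox1 (2.62) against Gpx1 (-1.60) and Prdx4 (-1.47). Glycolysis (13 tested) had 4 higher and 2 lower (Ldha, and Pfkp at -1.24), glutamate and GABA handling (6 tested) 3 higher (Gad1, Glul 2.06, Abat 0.84) and 2 lower, and the dissociation response (16 tested) 1 higher (Btg2, 0.77) and 8 lower, Egr1 (-0.99) and Jund (-0.68) among them. The cell cycle list had 1 of 18 higher (Hmmr, 1.78) and 2 lower (Mcm6 -1.53, Mcm5 -0.98), MHC class II 1 of 5 higher (H2-Eb1, 1.03, but -1.15 with clusters from the most variable genes and -0.51 with at least 1000 genes per cell), and Ghrl did not pass (-0.31). Adjusted over the list alone, the counts changed to 6 higher and 3 lower for transcription factors, 11 higher for glucose sensing, 7 higher for granules, 8 lower for duct, 0 higher and 1 lower for cell cycle, 2 higher and 9 lower for dissociation, and 1 lower for oxidative phosphorylation. Median and mean differed in sign for granules (-0.01 and 0.26), the immature list (0.26 and -0.68), glycolysis (0.05 and -0.06), antioxidants (-0.07 and 0.40) and autoantigens (-0.08 and 1.70). Camera adjusted p lay between 0.0611 and 0.986 for the other lists, 3 lists passed without mouse 2 and 8 without mouse 3, the duct, dissociation and adhesion lists among the 8. Classes taken from hormone UMIs alone gave 3237 genes and thinned cells 1197.

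Alpha-like cells were compared with delta-like cells in that fit as well. Ttr, the transthyretin gene (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321), stood at 23048 ± 3077 CPM (SD, n = 3) in alpha-like and 296 ± 206 in delta-like cells, an 85.8-fold difference (log2 6.42, SE 0.64, edgeR adjusted p = 0.00166). Lpl, the lipoprotein lipase gene (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448), was 53.3-fold higher in alpha-like cells (442.5 ± 44.9 against 9.90 ± 4.88 CPM). Delta-like cells held 159-fold more Pdyn, the prodynorphin gene (ENSMUSG00000027400, chromosome 2, 129686565 to 129699844), at 86.4 ± 10.0 against 0.787 ± 0.737 CPM (log2 -7.32, SE 0.36, adjusted p = 2.00e-06), and 105-fold more Cd44, a hyaluronan receptor gene (61.5 ± 8.65 against 0.650 ± 0.248 CPM). The other genes of the largest differences were Dapl1 (6.76), Vgf (6.07), Pdk4 (6.06), Tmsb15b2 (5.94), Higd1a (5.91), Nr4a2 (5.90), Tmsb15l (5.55) and Edn3 (5.20) toward alpha-like cells. Toward delta-like cells they were Ly6h (-7.25), Ppp1r17 (-7.20), Fam159b (-6.99), Mef2c (-6.94), Cd24a (-6.89), Dlk1 (-6.53), Nnat (-6.46) and Gap43 (-6.42). All 20 moved the same way in all 3 mice. At FDR 0.05, 2606 genes were higher and 2486 lower in alpha-like cells, 821 and 1124 of them at least 2-fold.

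The duct and acinar lists were lower in alpha-like than delta-like cells, and neither passed with free RNA subtracted or with clusters from the most variable genes. The duct list had 8 of 14 genes lower and 3 higher, with Slc4a4 (-2.80), Cldn7 (-1.34) and Epcam (-0.89) lower and Onecut2 (3.09) higher (camera adjusted p = 0.0350, and adjusted p = 0.611 with an estimated correlation). Its adjusted p was 0.164 with free RNA subtracted, 0.159 with clusters from the most variable genes and 0.0684 with at least 1000 genes per cell, and it did not pass without mouse 1 or without mouse 2. The endocrine progenitor list had 6 of 12 lower and 3 higher, with Neurog3 (-6.40), Insm1 (-1.45) and Sox11 (-7.77, with 0 UMIs in alpha-like cells, so that the fold depends on the prior count) lower and Gadd45a (2.27) higher. The acinar list had 12 of 18 lower and 0 higher, with Bhlha15 (-1.55), Pnliprp1 (-0.66), Cel (-0.62) and Ctrl (-0.60; adjusted p = 0.00514, and adjusted p = 0.617 with an estimated correlation), where acinar markers gave 0.257% of the UMIs of alpha-like and 0.634% of delta-like cells. With free RNA subtracted 1 of 18 acinar genes was lower (adjusted p = 0.806), and with clusters from the most variable genes 1 was lower with a median of -0.12 (adjusted p = 0.373). Pnliprp1 (0.53), Cel (0.56) and Ctrl (0.52) turned when classes came from hormone UMIs alone. Receptors (14 tested) had 8 lower, among them the urocortin receptor gene Crhr2 (-6.43), Sstr1 (-4.85) and Gcgr (-2.91), and 3 higher, among them the somatostatin receptor gene Sstr2 (4.78). Transcription factors of beta cells (11 tested) had 6 lower, with Mlxipl (-3.81), Insm1 and Rfx6 (-1.0), and 2 higher, with Nkx2-2 at 1.22. Cell adhesion and axon guidance (14 tested) had 7 lower, with Efna5 (-3.72), Cdh2 (-1.95) and Cdh1 (-1.61), and 3 higher, with Robo2 at 2.17.

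Of the lists of alpha against delta that remain, the cell cycle list passed and the others did not. Granule genes (18 tested) had 9 higher and 4 lower, with Vgf and Pcsk1n (1.28) against Nnat and Scg2 (-1.62), and oxidative phosphorylation (17 tested) 8 higher and 2 lower, with Cycs (0.73), Uqcrfs1 (0.48) and Atp5b (0.41). ER stress (20 tested) had 9 higher and 3 lower, with Atf3 (1.66), Atf4 (1.33) and Calr (0.65) against Edem1 (-1.40), and the dissociation response (16 tested) 6 higher and 4 lower, with Zfp36 (1.55) and Btg2 (0.87). The cell cycle list had 2 of 18 higher, Hmmr (2.11) and Pcna (0.76), and 0 lower (adjusted p = 0.0296, and adjusted p = 0.617 with an estimated correlation). With clusters from the most variable genes 4 of its genes were tested, the direction turned (median -0.26) and the call ended (adjusted p = 0.969). Antioxidant defence (20 tested) had 7 higher and 3 lower, with Hmox1 (2.31) and Prdx2 (0.52) against Cat (-2.69) and Gpx1 (-1.86), and glutamate and GABA handling (6 tested) 4 higher, Gad1 (1.56) and Glul (1.02) among them, and 1 lower. Autoantigens (7 tested) had 3 higher, Slc30a8 (5.02), Chga (2.76) and Gad1, and 1 lower, Ica1 (-0.76). Glucose sensing (18 tested) had 4 higher, with Slc30a8, Cacna1d (0.69) and Syt13 (0.41), and 4 lower, with Abcc8 at -0.80. Interferon and antigen presentation (19 tested) had 3 higher, B2m (0.98) among them, and 6 lower, with Ifit3 (-3.81), H2-T23 (-0.83) and Tapbp (-0.58). The disallowed list (9 tested) had 3 higher and 4 lower (Hk1 2.92 and Oat 2.83 against Acot7 -6.66 and Nfib -3.00), the immature list (7 tested) 3 higher and 2 lower (Serpina7 3.20 and Gpx2 0.59 against Dlk1), and the pancreatic progenitor list (4 tested) 2 higher and 1 lower (Gata6 1.56 and Hes1 0.80 against Nr5a2 -3.48). Glycolysis (13 tested) had 2 higher and 3 lower (Gapdh 0.41 and Pgam1 0.30, which turned with clusters from the most variable genes to -0.13 and -0.16, against Ldha -2.64 and Pkm -0.74), MHC class II (5 tested) 1 lower (H2-Eb1, -0.89, but 0.99 with classes from hormone UMIs alone), and Ghrl was lower (-1.05) in 2 of 3 mice. Adjusted over the list alone, the counts changed to 7 lower for endocrine progenitors, 13 lower for acinar, 1 higher for cell cycle, 10 higher for ER stress, 5 lower for dissociation, 0 lower for MHC class II and 9 higher for antioxidants. Median and mean differed in sign for the immature list (0.30 and -0.84), pancreatic progenitors (0.50 and -0.23) and autoantigens (-0.01 and 1.22), and the dissociation test pointed up against a median of -0.02. Camera adjusted p lay between 0.198 and 0.710 for the other lists, and 1 list passed without mouse 1, where the cell cycle and duct lists did not. DESeq2's Wald test called 3319 genes, classes from hormone UMIs alone 2907 and thinned cells 1118.

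Genes of non-endocrine pancreas cells were compared between beta-like cells and the mean of endothelial-like and macrophage-like cells, since the title asks about a non-endocrine origin. Epithelial genes of the duct list were higher in beta-like cells, while acinar genes lay below the free-RNA background that the reference cells give. Krt18, a keratin gene of simple epithelia, stood at 139 ± 22.8 CPM (SD, n = 3) in beta-like and 6.96 ± 0.764 in endothelial-like cells (log2 against the mean of both classes 3.72, SE 0.18, edgeR adjusted p = 1.44e-15). Of 9 tested duct genes 7 were higher, with Cldn7 (5.06), Epcam (3.87) and Krt8 (3.41) besides Krt18, and 2 were lower, Anxa3 (-7.80) and Tff2 (-0.82). Krt7, a duct marker used in clustering, was 5.22 log2 units higher (SE 0.23). Of 16 acinar genes 0 were higher, 14 lower and 2 not passing, with a median of -0.73. Acinar markers gave 1.15% of endothelial-like and 0.938% of macrophage-like UMIs against 0.281% in beta-like cells, without TMM. The lower values thus reflect a smaller share of such RNA and do not show that beta-like cells reduce acinar genes. Of 8 endocrine progenitor genes 4 were higher, Insm1 (4.71), Btbd17 (4.28), Hes6 (1.08) and Sox4 (0.74), and 1 was lower, Mfng (-5.55). Both tested pancreatic progenitor genes were lower, Procr (-4.43) and Hes1 (-3.30), but the reference cells hold Procr themselves, with a UMI in 18.6% of endothelial-like and 8.06% of macrophage-like cells against 1.22% of beta-like cells. Of the 35 tested genes 11 were higher and 19 lower at FDR 0.05 over 8253 genes, and without the mouse block 11 were higher and 4 lower. Adjusted over the list alone, endocrine progenitors had 5 higher, and the other counts stayed as given. Against alpha-like cells the duct list had 5 of 14 genes higher and 5 lower in beta-like cells. Without the filter on low counts, 20 of 63 genes were higher.

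**Figure D5:**
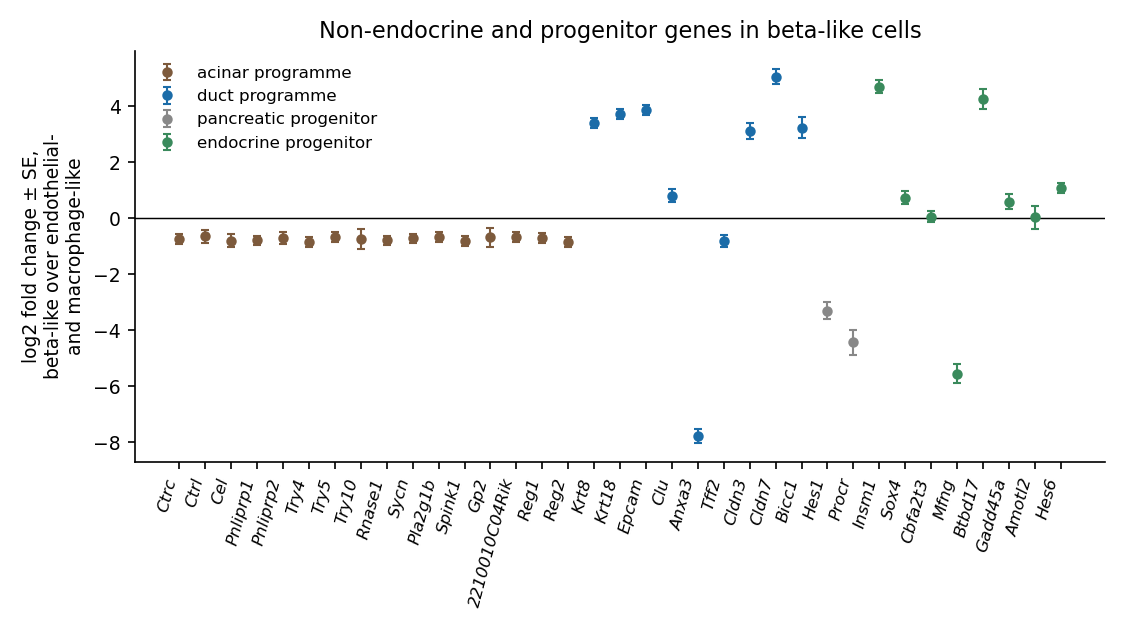
Log2 fold change (vertical axis) of acinar, duct and progenitor list genes in beta-like cells against the mean of endothelial-like and macrophage-like cells, with bars for the standard error. Acinar genes lie below 0 with a median of -0.73, and 7 of 9 duct genes lie above 0. For acinar genes the reference classes give the background of free RNA.

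Of the duct markers, Krt19 and Cftr were rare in beta-like cells. Krt19 had a UMI in 1.29% of beta-like cells (median 10633 UMIs), 74.9% of duct-like cells (median 7752 UMIs) and 0.532% of endothelial-like cells (median 4833 UMIs). Cftr, the duct chloride channel gene, was seen in 0.0718% of beta-like and 40.5% of duct-like cells. Spp1 was seen in 13.4% of beta-like, 98.3% of duct-like and 4.26% of endothelial-like cells and in 26 of 186 macrophage-like cells (median 7196.5 UMIs), and stood at 15.8 CPM without TMM in beta-like, 11.4 in endothelial-like and 47.0 in macrophage-like cells. Scaled by TMM, the levels were 30.4, 7.64 and 44.7 CPM (log2 against the mean of both reference classes 0.56, SE 0.24, edgeR adjusted p = 0.0478). Cells with at least 3 beta markers other than the hormones and at least 3 duct markers numbered 82 of 1648 beta-marker cells (5.60% ± 2.45; SD, n = 3), 0.832 ± 0.272 times the number that independent detection of both marker sets would give. The unrelated pairs gave 38 cells with endothelial markers (1.84% ± 1.34) and 9 with macrophage markers (0.562% ± 0.331). Their ratios to independent detection were 0.313 ± 0.224 and 0.177 ± 0.0486, so the duct pair lay above both. But Krt7, counted as a duct marker, had a UMI in 59.2% of beta-like cells. Slc2a2, counted as a beta marker, had one in 50% of the duct-like cells outside this pair. Acinar markers were found in 1642 of the 1648 cells, so that this pair distinguished nothing. Before doublets were removed, the duct pair numbered 95 of 1784 cells (6.14% ± 3.09). With at least 2 markers of each, the share of the duct pair was 25.3%.

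Few beta-like cells carried cell cycle transcripts. At least 3 genes of the cell cycle list were detected in 22 of 1393 beta-like cells (1.51% ± 0.489; SD, n = 3), 51 of 1350 alpha-like cells (5.69% ± 4.01), 25 of 887 delta-like cells (3.47% ± 1.56) and 42 of 351 duct-like cells (12.1% ± 1.66). Endothelial-like cells had 7 of 376 (1.47% ± 1.28) and macrophage-like cells 14 of 186 (7.29% ± 3.05). Mki67 or Top2a, genes of dividing cells, were among the detected genes in 12 of the beta-like, 26 of the alpha-like and 16 of the duct-like cells. Thinned to 2000 UMIs in total, of which hormones take more in some classes (insulin 63.1% in beta-like, Gcg 44.6% in alpha-like and Sst 19.4% in delta-like cells), the shares were 0.472% in beta-like, 1.73% in alpha-like, 0.645% in delta-like and 2.73% in duct-like cells. The depth left for other genes was therefore not equal. With at least 2 genes the share of beta-like cells was 5.97%. Cells are not replicates, so these shares were not tested.

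More than 1 hormone above background was found in 1199 of 5344 hormone-positive cells (23.3% ± 10.8; SD, n = 3), with shares of 20.9%, 35.1% and 13.9% in mice 1, 2 and 3. The commonest pair was insulin with Sst, in 634 cells, of which 522 came from mouse 2. In that mouse the background was 0.0841% for Sst against 3.75% for insulin. The pair fell to 284 cells with 10 times the background as the limit. Of 158 acinar-like cells, a non-endocrine class, 53 also passed the limit for Sst. Passing it therefore does not show that a cell makes the hormone, and the part of free RNA in these counts stays open. The share of all cells of a class was highest among the named classes in gamma-like cells, where 86 of 280 (30.7%) had at least 2 hormones and 82 had Gcg with Ppy. It was 17.5% in delta-like, 14.6% in beta-like and 5.19% in alpha-like cells. Unnamed cells gave 659 of the 1199. With doublets kept they were 1221 of 5488 hormone-positive cells, and with 10 times the background as the limit the share was 13.8% ± 5.97. The planned comparisons of gamma-like with alpha-like and delta-like cells were not run, because mouse 2 held 13 gamma-like cells, under the minimum of 20.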

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

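All alternatives but the minimum of 5000 UMIs and those of the gamma-like and duct-like comparisons, which were chosen after the data were seen, were fixed before the data were examined. Of 300 gene results, 29 turned direction in at least 1 setting. Over all settings other than leaving out a mouse, 3560 of 3785 gene values kept direction and side of the threshold, 159 lost the call, 32 gained it and 34 turned. Leaving out a mouse turned 0 of 894 gene values, ended 38 calls and added 10. Of 249 list values, 227 stayed on their side, 18 lost and 4 gained a call, and leaving out a mouse ended 6 and added 7 of 189. Of 81 further cell shares, 18 moved by over 1 SD. Depth limits the calls, as cells thinned to 2000 UMIs left 5868 of 12185 genes to test. The contrasts of gamma-like cells planned with at least 20 cells per mouse, and their alternatives, were not run.

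Counts of called genes moved by over 1.5 times in these settings. The DESeq2 Wald test gave 3884 for beta against alpha and 3319 for alpha against delta. Thinning gave 1529, 1197 and 1118 for beta against alpha, beta against delta and alpha against delta, where fewer genes were tested. Classes from hormone UMIs alone gave 3237 for beta against delta and 2907 for alpha against delta. With an estimated correlation 0 lists passed in each of the 3 contrasts, and with free RNA subtracted 1 passed for alpha against delta. Without the filter on low counts 20 non-endocrine genes were higher in beta-like cells, as more genes were tested. Without the mouse block gamma against alpha gave 1001, the non-endocrine genes lower in beta-like cells fell from 19 to 4, and the lists lower for beta against delta rose from 2 to 4. The share of alpha-like cells was 27.6% with at least 5000 UMIs. The share of beta-like cells was 11.4% with at most 10% mitochondrial UMIs, 10.6% with the 2000 most variable genes and 10.8% at resolution 0.5, and that of duct-like cells 2.70% with the most variable genes. Cells with beta and duct markers made up 25.3% with at least 2 markers of each, and cycling beta-like cells 5.97% with at least 2 genes and 0.472% when thinned. Where no reason is given, the cause was not tested.

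With each mouse left out in turn, called genes ranged from 4491 to 5689 for beta against alpha, 3925 to 5336 for beta against delta and 3599 to 4956 for alpha against delta. Lists past the threshold ranged from 3 to 6, 3 to 8 (3 without mouse 2, 8 without mouse 3) and 1 to 3 (1 without mouse 1). Non-endocrine genes higher in beta-like cells ranged from 10 to 12, gamma against alpha from 659 (without mouse 3) to 1355, gamma against delta from 1304 (without mouse 3) to 2931, and duct against endocrine from 7443 to 7954. Shares ranged from 12.5 to 20.4% for alpha-like, 18.6 to 26% for beta-like, 7.96 to 13.1% for delta-like and 4.46 to 6.34% for duct-like cells, 1.29 to 1.77% for cycling beta-like cells and 17.4 to 28.0% for cells with more than 1 hormone.

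The genes that turned direction have these log2 fold changes, and the cause was not tested. Of the 34 turned values 19 came with classes from hormone UMIs alone, where the insulin class is mixed and holds 1260 beta-like, 208 duct-like, 130 endothelial-like, 86 macrophage-like and 851 unnamed cells among others. With classes from hormone UMIs alone, beta against alpha gave Arap2 0.78, Krt8 0.17, B2m 1.57, Bst2 1.84, H2-K1 1.30 and Psmb8 0.45. Beta against delta gave Arap2 0.14, Ldha 2.04, Gata6 0.092, Nr5a2 0.77, Cldn3 0.90, Clu 0.73, H2-D1 0.28, H2-K1 1.17 and Psmb8 0.20, and alpha against delta gave Pnliprp1 0.53, Cel 0.56, Ctrl 0.52 and H2-Eb1 0.99. With clusters from the most variable genes, beta against alpha gave Ghrl -0.21, Pnliprp1 -0.31, Cel -0.30, Ctrl -0.28 and H2-Eb1 -0.24, beta against delta H2-Eb1 -1.15 and Ldhb -0.27, and alpha against delta Gapdh -0.13 and Pgam1 -0.16. With at least 1000 genes per cell, beta against alpha gave Ghrl -0.19, Pnliprp1 -0.47, Cel -0.56 and Ctrl -0.41, and beta against delta H2-Eb1 -0.51. Thinned cells gave Ptprn2 0.052 for beta against alpha.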

Other observations

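Chosen only after the results were seen were the gamma-like and duct-like comparisons, the tests of shallow cells, of free RNA and of the level of Fam241b for Neurog3, the genes singled out in the last paragraph and the tests by other splits of the samples.

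Gamma-like cells were compared with alpha-like and delta-like cells in a fit that took classes with at least 10 cells per mouse. Folr1, a folate receptor gene (ENSMUSG00000001827, GRCm38/mm10 chromosome 7, 101858331 to 101870788), stood at 447 ± 86.6 CPM (SD, n = 3) in gamma-like and 39.3 ± 9.07 in alpha-like cells (log2 3.57, SE 0.18, edgeR adjusted p = 1.76e-07). S100a10 (2.84), the tetraspanin gene Cd9 (2.60), Clu (2.58), Hspb1 (2.53), Snhg18 (2.43), Sult1d1 (2.07), the calbindin gene Calb1 (2.02) and Hadh (1.93) were also higher. Ttr was lower, at 4475 ± 1606 against 22781 ± 3046 CPM (log2 -2.35, SE 0.55, adjusted p = 0.0379), with Dapl1 (-3.58), Vgf (-2.91), Spc25 (-2.49), Gem (-2.33), Higd1a (-1.98), Oxtr (-1.91), the zinc transporter gene Slc30a8 (-1.91), Nr4a2 (-1.80) and Cryba2 (-1.79). Against delta-like cells Ugt2b34 (5.32) and Lpl (4.74) were among the highest, and Ppp1r17 (-7.66), Ptn (-7.13) and Dlk1 (-6.37) lowest. Of 12258 genes tested, 820 were higher and 871 lower than in alpha-like cells, and 1667 were higher and 1601 lower than in delta-like cells. Against alpha-like cells the cell cycle list was lower (2 of 18 genes lower, camera adjusted p = 0.00263) and the duct list higher (8 of 14 higher and 1 lower, 0.0077), and with an estimated correlation their adjusted p were 0.839 and 0.411. Against delta-like cells the acinar list was lower (5 of 18, 0.0226) and ER stress and protein folding higher (9 of 20 higher and 1 lower, 0.0261), with 0.654 and 0.567 at an estimated correlation. The other lists lay between 0.481 and 0.982 against alpha-like and between 0.0789 and 0.825 against delta-like cells. Most gamma-like cells (245 of 280) came from mouse 3, and without it the calls fell to 659 and 1304.

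Duct-like cells differed from the mean of beta-like, alpha-like and delta-like cells in most genes tested. Cp, the ceruloplasmin gene (ENSMUSG00000003617, GRCm38/mm10 chromosome 3, 19957054 to 20009145), stood at 1094 ± 99.4 CPM (SD, n = 3) against 1.31 ± 1.06 (log2 9.97, SE 0.20, edgeR adjusted p = 5.29e-11). Msmp (1418 ± 452 CPM), the secreted antimicrobial gene Lcn2 (552 ± 378 CPM), Wfdc18 (832 ± 418 CPM) and Ces1d (264 ± 41.0 CPM) were also higher, as were Ankrd1, Krt17, Sbspon, Ltb and Crp. Resp18, an endocrine granule gene, was lower at 53.8 ± 19.3 against 3469 ± 1393 CPM (log2 -5.87, SE 0.32, adjusted p = 3.52e-06), and so were the islet transcription factor gene Isl1 (-5.79), Rgs4 (-6.49), Vwa5b2 (-5.94), Sez6l2 (-5.90), Celf3 (-5.87), Slc7a14 (-5.87), Pcsk2os1 (-5.80), Syndig1l (-5.70) and Stk32a (-5.60). Of 13084 genes tested, 4247 were higher and 4349 lower in duct-like cells.

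Acinar list genes were higher in beta-like than alpha-like cells for 14 of 18 genes. Of the 13 called genes other than Bhlha15, 92.3% (12) held a share of the list's UMIs within 2-fold of that in the removed barcodes in every mouse, the profile that free RNA from acinar cells would give. With free RNA subtracted the median log2 fold change of the list rose from 0.62 (SD over genes 0.54) to 1.11 (SD 0.61), while the genes called fell from 14 to 1, as the median SE rose from 0.15 to 0.83. The profile subtracted was that of all barcodes of a library. Kept cells gave 67.4%, 87.1% and 87.3% of its UMIs in mice 1, 2 and 3. It is therefore not a profile of free RNA alone, and the rise cannot decide on free RNA. Scaling plays a part as well, since the TMM factors were 0.695, 0.605 and 0.730 for beta-like and 0.947, 0.887 and 1.07 for alpha-like sums. RNA at an equal share of UMIs thus reads as higher in beta-like cells. The acinar markers used in clustering made up 0.247%, 0.545% and 0.0499% of beta-like UMIs in mice 1, 2 and 3. In alpha-like cells they made up 0.1645%, 0.541% and 0.0673%. Before scaling, the beta-like share was thus higher in mouse 1, near equal in mouse 2 and lower in mouse 3. Scaling alone would raise RNA of equal share, so the 14 calls do not show a larger share of acinar RNA in beta-like cells. Whether free RNA is the source of the enzyme genes therefore stays open. For Bhlha15, a secretory cell transcription factor gene, the share of the list's UMIs in beta-like cells was at least 20.7 times that in the removed barcodes. This argues against acinar RNA of the removed barcodes' profile as its whole source. Those barcodes may hold damaged cells besides free RNA. The median was -0.50 with at least 1000 genes per cell but 0.44 with at least 5000 UMIs, and 1.83 in cells thinned to 2000 UMIs, so that the part of shallow cells in the beta-like class stays open too. What raises Bhlha15 in beta-like cells stays open, and no biological explanation was tested, since the design has 1 group.

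Neurog3 (chromosome 10, 62133090 to 62134763) was read at 52.8 CPM in delta-like cells, 39.6 times the level of the highest other named class, which argues against free RNA. Outside the delta-like class the highest level of a cluster was 8.30 CPM, against at least 47.2 in the 3 delta-like clusters, which argues against doublets with another cell. 1 annotated gene, Fam241b (chromosome 10, 62107655 to 62143920, opposite strand), overlaps it, but the ratio of Neurog3 to Fam241b was at least 10.9 times higher in delta-like than in beta-like, alpha-like or duct-like cells, which argues against reads shared in proportion to Fam241b. The log2 difference to beta-like cells was -3.88 with doublets kept and -3.99 in thinned cells. Transcription of Neurog3 in delta cells of adult NOD-SCID islets may be a biological feature, as a hypothesis found and tested on the same data; no biological explanation was tested, since the design has 1 group.

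Cells with beta and duct markers numbered 35 in the duct-like and 30 in the beta-like class. The median insulin share of those in the duct-like class was 0.204 times that of other duct-like cells (0.562% against 2.76%, with 56.4% in beta-like cells), and the duct marker share of those in the beta-like class was 0.811% of that of duct-like cells, both of which argue against doublets of a beta-like and a duct-like cell. Both groups are deeper than their classes, with medians of 38550 against 7752 UMIs in the duct-like and 83459.5 against 10633 in the beta-like class. Thinned to 2000 UMIs, 0 of the 35 and 0 of the 30 kept both marker sets, which thinning this far would give whatever the source, so the part of depth stays open. Krt7, a duct marker, had a UMI in 59.2% of beta-like and 54.4% of duct-like cells, so it does not tell the classes apart. Slc2a2, counted as a beta marker, had a UMI in 91.4% of the 35 cells but also in 50% of other duct-like cells. Pdx1 had one in 85.7% and 16.8%, and Mafa in 34.3% and 8.86%. Without the 3 duct markers that over 5% of beta-like cells hold, 0 of the 30 and 32 of the 35 were left. The 30 cells thus rest in part on duct markers that other beta-like cells hold. The 5% limit was not applied to the beta markers. Besides Slc2a2, Pdx1 and Mafa, G6pc2 (7.59%) and Sytl4 (6.65%) exceed it in other duct-like cells. Without these, fewer than the 3 required beta markers would remain. The 35 cells likewise rest in part on beta markers that other duct-like cells hold. No biological explanation was tested.

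Other splits of the sums were fitted with the same tests in fits of the compared sums alone. Beta against alpha gave 5737 genes, beta against delta 5239, alpha against delta 5195, gamma against alpha 1683 and gamma against delta 2532. In each, 1 of the 10 splits, the real one, gave as many, and the highest other gave 0, also among the splits that part the sums of all 3 mice (4 of 10 with the real one); 10 splits are too few for a share under 0.05. For non-endocrine genes higher in beta-like cells, 1 of the 81 splits that could be fitted, the real one, gave 8, and the highest other gave 2; 3 splits could not be fitted. For duct against endocrine cells, 1 of 60 splits gave 6047 and the highest other 0. The classes were made from the expression of the same cells, so the real split was bound to give the most genes, and these splits do not settle the part of chance.

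Cd79a, a B cell receptor gene (ENSMUSG00000003379, chromosome 7, 24897381 to 24902197), had a UMI in 220 of 1393 beta-like cells (15.8%, exact 95% interval 13.9 to 17.8; median 10633 UMIs), 6.59% of alpha-like cells and 2 of 376 endothelial-like cells (0.532%; median 4833 UMIs), while Ms4a1, another B cell gene, had 0 UMIs in every named class and 1 UMI in the unnamed cells. Fev, a serotonin neuron and endocrine progenitor factor gene, had a UMI in 36.9% of alpha-like (median 21624 UMIs), 36.1% of gamma-like (22406.5), 17.9% of delta-like (10674) and 2.44% of beta-like cells, against 1.86% of endothelial-like cells. Thinned to 2000 UMIs in total, which does not level the depth left beside the hormones, the shares were 4.72%, 5.40%, 4.27%, 0.307% and 0.872%, and the levels were 21.7, 23.7, 19.2, 0.988 and 3.65 CPM.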
